A study of Cubamyces sp. BRFM 1775 with 14 samples.

How the data were processed

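Messenger RNA was measured by RNA sequencing in mycelium of Leiotrametes sp. BRFM1775. Per the labels' protocols, the fungus grew for 3 days at 30 °C and 120 rpm in flasks with 100 ml of a mineral medium. The medium held 20 g/l maltose, or 2.5 g/l maltose with 15 g/l cellulose, wheat straw or pine. Aspen was also added at 15 g/l, but the maltose concentration of those cultures is misprinted in the labels. Mycelium was frozen together with the remaining solid substrate. Per the labels' protocols, polyadenylated RNA was made into cDNA fragments of 200 to 300 bp and sequenced on an Illumina HiSeq instrument as paired reads of 150 bp. Whether the replicates came from separate flasks is not stated, so p-values measure only the spread between these libraries, which may be technical.

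The deposited table holds 1 column per substrate with a normalised log2 read count, per the file headers, for 1052 genes identified by protein numbers of the MycoCosm genome portal. Per the submitters' processing notes, TopHat2, HTSeq and DESeq (version 1.5) were used, with no role or order given. The genome build, the constant added before the log, the rule that chose the 1052 genes and the way libraries were combined are not given in the sources used here. The values were first examined for what they contain. If a deposited value is the mean over libraries of log2(reads × scale + 1), with whole reads and 1 scale per library, then a few low values fix the scales. Scales were searched on the 16 lowest values of each column, then refined and checked on the 60 lowest. The values checked were thus not held out from the fit of the scales. In every column all 60 values came out as whole reads within 1e-09, and 0 of 60 did with the scales moved 1% up or down. The maltose, pine and aspen columns needed 3 libraries, and the cellulose and wheat straw columns needed 2. The labels list 3 cellulose samples, and which of them is absent from the column is not known.

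With the scales fixed, each gene's reads were solved in every library and kept where exactly 1 set of whole numbers matched the deposited value. For deposited values above 6, the search was limited to a 16-fold range per library around that value, so matches outside it were not looked for. This gave the reads of 886 genes on maltose, 1048 on cellulose, 1049 on wheat straw, 778 on pine and 794 on aspen, and of 707 genes in all 13 libraries. Genes with a deposited value above 12 were not attempted in columns of 3 libraries, because several solutions become possible. Libraries are numbered by size factor within a substrate, from the lowest, and these numbers are not the replicate numbers of the labels. In a simulated column of 2 libraries 1050 of 1052 genes were solved, and in one of 3 libraries 791, all of them with the right reads. In a column of aspen values with noise added, 3 of the 60 lowest values came out whole. Read numbers of libraries of a substrate differed by more than sampling noise in every pair (chi-square per degree of freedom of at least 10.6), so none was counted as a duplicate.

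The comparisons were planned before the data were examined, for 1 value per library and 14 libraries. They were carried out on the recovered log2 values with limma 3.58.1 in R 4.3.3: a mean per substrate, all libraries in 1 fit, a moderated test with a trend of the spread over levels, and Benjamini-Hochberg adjustment within each comparison. The mean of a substrate equals the deposited log2 value for every gene. Where the libraries of a substrate were not solved for a gene, the deposited mean was kept and the gene's spread came from its other substrates. A call needed an adjusted p below 0.05 and a log2 difference of at least 1. Differences are on the log2(normalised reads + 1) scale, which understates the change of genes with few reads. Without any test, a log2 difference of at least 1 in the deposited values was reached by 287 genes on cellulose, 419 on wheat straw, 563 on pine and 509 on aspen against maltose. Reads were recovered with Python 3.11.15, NumPy 2.4.6 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9.

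The fit was tested on reads simulated for the 13 libraries, with 200 of 1052 genes changed. For cellulose minus maltose, it called 27 of 67 genes changed 2-fold, 54 of 67 changed 4-fold and 62 of 66 changed 8-fold, with 3 of 852 unchanged genes called. For pine minus maltose, the numbers were 24 of 67, 56 of 67 and 64 of 66, with 4 of 852 unchanged genes called. Overlaps of calls with the shared maltose libraries were set against 50 simulated tables without change.

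The genes named were those with the largest called differences in each direction whose libraries were solved and did not overlap between the substrates compared. Since the table does not pair protein numbers with names, at most 2 genes per direction and comparison are given, as the rule fixed for that case, and the gene lists planned by enzyme family were not tested. Sets of genes were formed from the calls after the calls were seen. The alternatives planned were the spread without a trend, only the libraries compared, leaving out the genes of lowest level (25%), 32 normalised reads added before the log, centring each library on its median, quantile normalisation, library weights, both other call thresholds and leaving out each library. Added after the data were seen were a fit on the 707 genes solved in all libraries and a shift of each library by its median difference from the gene means (the median shift). A fit with the replicate number as a block was planned and could not be made.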

Results

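Mycelium of Leiotrametes sp. BRFM1775, a wood-decaying fungus of the order Polyporales that GEO lists as a Cubamyces species, was grown for 3 days on 5 carbon sources, and its messenger RNA was sequenced. The control cultures held maltose, a soluble sugar, as the main carbon source. The others held microcrystalline cellulose, wheat straw (a grass), ground pine (a softwood) or ground aspen (a hardwood). The cultures on cellulose, wheat straw and pine also held a smaller amount of maltose, and for aspen the labels misprint the amount. Comparing cellulose, wheat straw or pine with maltose therefore also changes the maltose concentration, from 20 g/l to 2.5 g/l. The design does not separate this from the added substrate, and for aspen the change in maltose is not known. The labels list 14 samples: 3 each on maltose, cellulose, pine and aspen, and 2 on wheat straw. The deposited table gives 1 mean log2 normalised read count per substrate for 1052 genes, named by protein number only. The read numbers of single libraries were recovered from these means, and they account for 13 libraries, with 2 on cellulose and the labelled number on each other substrate. The table does not pair the gene numbers with names, so genes are described by number and by how they behaved across substrates, and no gene family is named.

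Expression spanned a wide range on every substrate. The deposited log2 values ran from 0 to 18.3, and their median over genes was 8.30 on maltose, 8.92 on cellulose, 9.20 on wheat straw, 9.30 on pine and 9.13 on aspen. On maltose the 10 most abundant genes made up 32.2% of the sum of the deposited values, taken back from the log2 scale. This share was 23.1% on cellulose, 26.5% on wheat straw, 22.9% on pine and 23.2% on aspen. Because the deposited values are means of log2 values, these are not shares of the reads of any library. Of the 10 genes most abundant on pine, 5 were also among the 10 most abundant on aspen, but only 2 among those on maltose. Pine was the substrate with the highest value for 353 genes, cellulose for 226, aspen for 208, maltose for 173 and wheat straw for 92. These counts hold for the deposited scaling and were not repeated under others. The scaling matters for them: the median difference over genes, pine minus maltose, was 0.56 as deposited and -0.40 with each library centred on its median. The size factors of the recovered libraries lay between 0.426 and 1.61, and the median gene with recovered reads had between 95 and 797 reads per library. The median standard deviation (SD) between libraries of a substrate was 0.19 on maltose, 0.29 on cellulose, 0.17 on wheat straw, 0.31 on pine and 0.23 on aspen, in log2 units. Pearson correlations over genes between libraries of a substrate lay between 0.945 and 0.989, where genes are not independent replicates.

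The libraries grouped by substrate. The first principal component held 52.8% of the variance over 707 genes and placed the libraries in the order maltose, cellulose, wheat straw and then the woods. The second component, with 18.5%, had cellulose at one end and maltose at the other, and the third, with 8.94%, set pine apart from aspen. Over all 1052 genes, 854 differed among the 5 substrates by limma's F test at the adjusted p threshold of 0.05. A gene was called between 2 substrates when its adjusted p was below 0.05 and its log2 difference was at least 1, and 783 genes were called in at least 1 of 9 comparisons. The remaining 269 genes were called in none.

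**Figure D1:**
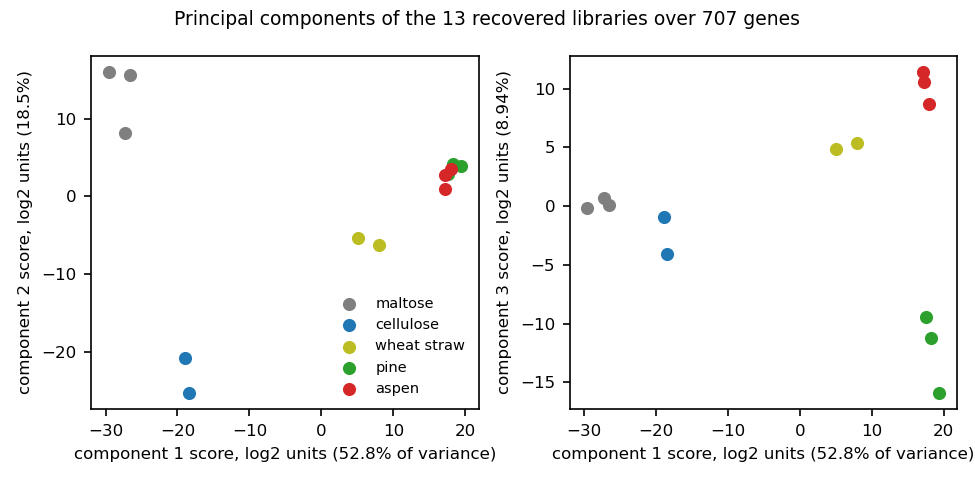
Scores of the 13 recovered libraries on principal components 1 and 2 (left) and 1 and 3 (right), in log2 units, over 707 genes, with 1 point per library coloured by substrate. Pine and aspen lie together on component 1 and part on component 3, which holds 8.94% of the variance.

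**Figure D2:**
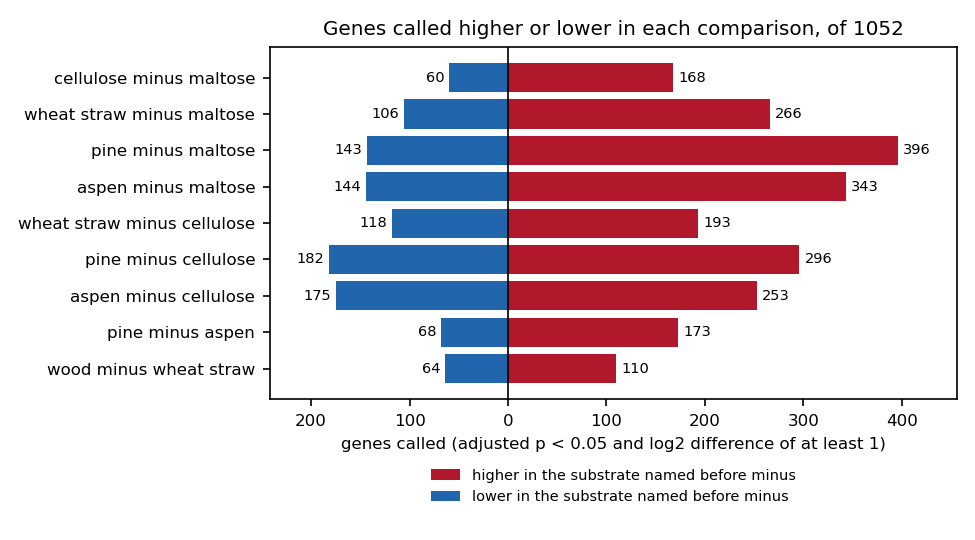
Number of genes called higher (right of 0) or lower (left of 0) in each of 9 comparisons, of 1052 genes, at an adjusted p below 0.05 and a log2 difference of at least 1. Pine against maltose gave the most calls, 396 higher and 143 lower, and wood against wheat straw the fewest.

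The comparison of cellulose with maltose asked which genes differ on a purified plant polysaccharide with less maltose. Here 168 genes rose on cellulose and 60 fell, with median log2 changes of 2.29 and -1.48. The rises were the larger ones: 97 genes rose and 16 fell at least 4-fold, and 35 rose at least 64-fold, while none fell that much. Gene 1319085 rose by 9.57 (SE 1.31, adjusted p = 0.000598), from 2 to 59 reads per maltose library (SD 2.93 over 3) to 11505 and 12400 reads in the cellulose libraries. Gene 1250928 rose by 9.39 (SE 1.22, adjusted p = 0.00141), from 5 to 49 reads up to 9966 and 15781 reads. Both were also higher on each of the 3 plant materials, at deposited values between 10.5 and 12.8. Maltose library 1 stood apart for such genes: of the 51 that rose at least 16-fold, 47 had their highest maltose value in it, by a median of 1.86 over the mean of the other maltose libraries, against 368 of all 886 solved genes and 0.05. Without it genes 1319085 and 1250928 rose by 11.22 and 10.79. It also had the highest correlations of the maltose libraries with the cellulose libraries, 0.854 and 0.878. The same held for its correlations with every wheat straw, pine and aspen library. The cause was not tested. Among the genes that fell, gene 1272555 was at 7.37 on maltose (SD 0.22 over 3 libraries) and 4.30 on cellulose (SD 0.49 over 2), a change of -3.07 (SE 0.78, adjusted p = 0.0136). Gene 1325741 changed by -2.96 (SE 0.76, adjusted p = 0.0139), but missed the size threshold at -0.88 once 32 reads were added to every value, since it had at most 7 reads in a cellulose library. Leaving out cellulose library 2 ended the calls of both falling genes, with differences of -2.72 and -2.23. The share of calls that were higher was 73.7%, and it was 35.5% with each library centred on its median and 44.8% after quantile normalisation.

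On wheat straw, a whole plant material, more genes were called than on cellulose: 266 were higher and 106 lower than on maltose, with median log2 changes of 2.47 and -1.86. At least 4-fold, 166 rose and 48 fell, and 27 rose at least 64-fold. The largest rise among genes with separated libraries was 9.98 (SE 0.68, adjusted p = 4.69e-06) for gene 1434891, which had 3 to 6 reads in each maltose library and 5776 and 12662 in the straw libraries. This gene stood at 10.65 on cellulose, 9.75 on pine and 12.45 on aspen. Gene 1328619 rose by 8.73 (SE 1.29, adjusted p = 0.00136) to 15.40 on wheat straw, by 10.18 without maltose library 1, and was at 15.66 on cellulose. Gene 1334166 fell by 6.47 (SE 0.59, adjusted p = 7.31e-06), from 11.20 on maltose (SD 0.42 over 3 libraries) to 4.73 on wheat straw (SD 0.41 over 2). Its values were 12.93 on cellulose, 9.62 on pine and 8.25 on aspen, so that wheat straw gave the lowest of the 5. Gene 1272555, which fell on cellulose, fell further here, by 4.73 (SE 0.78, adjusted p = 0.000512). The share of higher calls was 71.5%, against 33.0% with median centring and 40.4% after quantile normalisation. Without wheat straw library 2 the lower calls numbered 67, against 106 on the same genes.

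Pine, a softwood, gave the most calls of any comparison, 396 genes higher and 143 lower than on maltose. The median changes were 2.33 and -1.96, and 252 genes rose and 68 fell at least 4-fold. Gene 1261529 rose by 8.96 (SE 0.60, adjusted p = 3.77e-07), from 0 to 11 reads per maltose library to between 1022 and 1667 reads on pine. It stayed near the floor on cellulose, at 3.43, and reached 9.71 on wheat straw and 8.75 on aspen. Gene 1294900 rose by 7.64 (SE 0.26, adjusted p = 5.22e-09) to 11.59 (SD 0.17 over 3 libraries). In the other direction, gene 1439293 fell by 6.35 (SE 0.37, adjusted p = 1.86e-07), from 8.27 on maltose to 1.92 on pine, where it had 2 to 3 reads per library. Gene 1312252 fell by 6.19 (SE 0.36, adjusted p = 1.86e-07) to 1.36. The median difference over all genes was 0.56, but -0.40 with median centring, -0.18 after quantile normalisation and 0.06 with each library shifted by its median difference from the gene means. The share of higher calls was 73.5%, and it was 41.0% with median centring, 44.9% after quantile normalisation and 55.4% with that shift. On the 778 genes solved on pine the share was 62.75%. Of all 539 calls, 340 were on genes solved on both pine and maltose. For the others the library spread of at least 1 of these substrates is missing.

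On aspen, a hardwood, 343 genes were higher and 144 lower than on maltose, with median changes of 2.41 and -1.97, and 31 genes rose at least 64-fold. Gene 1344631 rose by 8.33 (SE 1.02, adjusted p = 3.81e-05), from 0 to 20 reads per maltose library to between 2389 and 3724, and by 9.63 without maltose library 1. It was also high on cellulose, at 11.50, and on wheat straw, at 11.22. Gene 1294900 rose by 7.77 (SE 0.26, adjusted p = 8.76e-09), close to its rise on pine. Gene 1439293 fell by 6.77 (SE 0.37, adjusted p = 1.64e-07) to 2 reads per aspen library, and gene 1272555 fell by 6.48 (SE 0.70, adjusted p = 1.38e-05). The maltose concentration of the aspen cultures is misprinted in the labels, so it is open whether aspen differed from the other plant materials in added sugar. The share of higher calls was 70.4%, against 41.4% with median centring, 43.8% after quantile normalisation and 56.6% with the median shift. On the 794 genes solved on aspen the share was 61.68%. Of all 487 calls, 305 were on genes solved on both aspen and maltose, and for the others the library spread of at least 1 is missing.

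Genes were then grouped by their calls across substrates. A group of 103 genes rose on all 4 other substrates against maltose, by a median of 3.51 on cellulose, 4.46 on wheat straw, 3.66 on pine and 3.85 on aspen, and 18 genes fell on all 4. A group of 113 genes was higher on each of the 3 plant materials than on both maltose and cellulose. Their median difference from maltose was 2.63 on wheat straw, 3.47 on pine and 3.17 on aspen, but 0.14 on cellulose. The mirror group of 36 genes was lower on all 3 plant materials than on both, with medians of -2.28, -2.85 and -3.33, and -0.19 on cellulose. A group of 40 genes was higher on cellulose than on each of the other 4 substrates, with a median rise of 2.24 over maltose. Pine and aspen shared the most calls in number: 295 genes rose and 106 fell on both against maltose, where independent lists of those lengths would share 129.1 and 19.6. Wheat straw and aspen shared 232 rises and 81 falls, against 86.7 and 14.5. This is more relative to independent lists, but a pair with shorter lists can reach a higher ratio. Cellulose and pine shared 124 rises, against 63.2 for independent lists, and 29 falls, against 8.16. In 50 simulated tables of unchanged groups that shared simulated maltose libraries, the mean number of shared rises or falls was at most 0.02 for any pair of substrates. No simulated comparison with maltose had more than 2 calls, so almost none could be shared. These counts therefore do not measure the overlap to be had among as many calls as were made here. The covariance of the differences was 4.15 for pine and aspen, 3.8 for wheat straw and aspen and 1.94 for cellulose and pine. In the simulated tables it was 0.0628, 0.0638 and 0.0646. The 3 maltose libraries were too few to be split, and part of the excess may come from sharing them. Under median centring the groups of 103, 18, 113 and 36 genes became 64, 75, 72 and 77, and without wheat straw library 2 the group of 36 became 20.

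**Figure D3:**
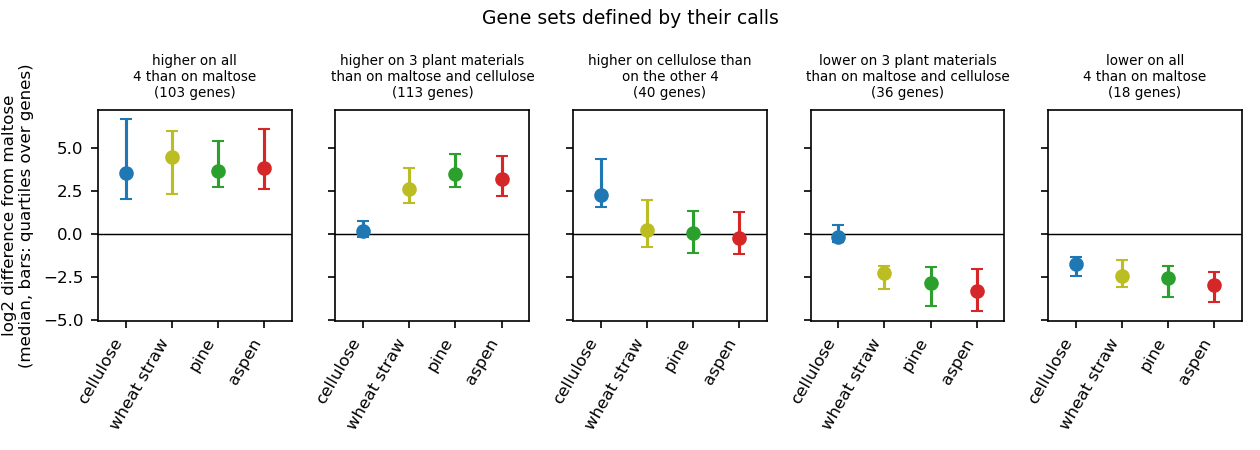
Median log2 difference from maltose (points) and quartiles over genes (bars) on cellulose, wheat straw, pine and aspen, for 5 gene sets defined by their calls. The 113 genes of the second panel lie at 0.14 on cellulose and between 2.63 and 3.47 on the plant materials, and the 40 genes of the third panel lie at 2.24 on cellulose.

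The plant materials were compared with cellulose to separate responses to whole plant cell walls from those to the polysaccharide alone. Against cellulose, 193 genes were higher and 118 lower on wheat straw, 296 higher and 182 lower on pine, and 253 higher and 175 lower on aspen. On all 3 materials, 147 genes were higher and 85 lower than on cellulose. Gene 1330893 was higher on wheat straw by 8.99 (SE 0.52, adjusted p = 3.51e-05), from 19 and 34 reads on cellulose to 11432 and 22343. It was at 15.65 on pine and 13.89 on aspen, and at 5.65 on maltose. Gene 1277688 was higher on wheat straw than on cellulose by 6.68 (SE 0.54, adjusted p = 0.000126). Gene 1410238 was higher on pine by 7.28 (SE 0.44, adjusted p = 5.86e-07) and on aspen by 6.26 (SE 0.44, adjusted p = 1.73e-06), with 2 and 6 reads in the cellulose libraries. Gene 1261529, already named for its rise on pine against maltose, was higher on pine than on cellulose by 7.10 (SE 0.67, adjusted p = 7.64e-06), and gene 1273914 was higher on aspen by 5.55 (SE 0.70, adjusted p = 7.35e-05).

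The genes lower on plant material than on cellulose included some of the most abundant cellulose transcripts. Gene 1369948 had 24926 and 96994 reads in the cellulose libraries and 208 to 375 in the wood libraries, a difference of -6.89 (SE 0.98, adjusted p = 0.00014) on pine and -7.45 (SE 0.98, adjusted p = 0.000105) on aspen. Gene 379663 was lower on pine, at a difference of -6.63 (SE 1.05, adjusted p = 0.000293), and gene 1375213 was at 10.43 on cellulose and 2.37 on aspen, a difference of -8.06 (SE 0.43, adjusted p = 5.82e-07). Gene 1334166 was lower on wheat straw than on cellulose, with a difference of -8.20 (SE 0.64, adjusted p = 1.17e-05), and so was gene 1370799, with -5.89 (SE 1.00, adjusted p = 0.00174). The SD of some of these genes between the 2 cellulose libraries was large, at 1.69 for gene 1334166 and 1.47 for gene 1369948. The share of higher calls was 62.1% on wheat straw and 61.9% on pine, against 47.9% and 50.9% with median centring. Without wheat straw library 2 the genes lower on wheat straw than on cellulose numbered 70, against 118 with it.

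**Figure D4:**
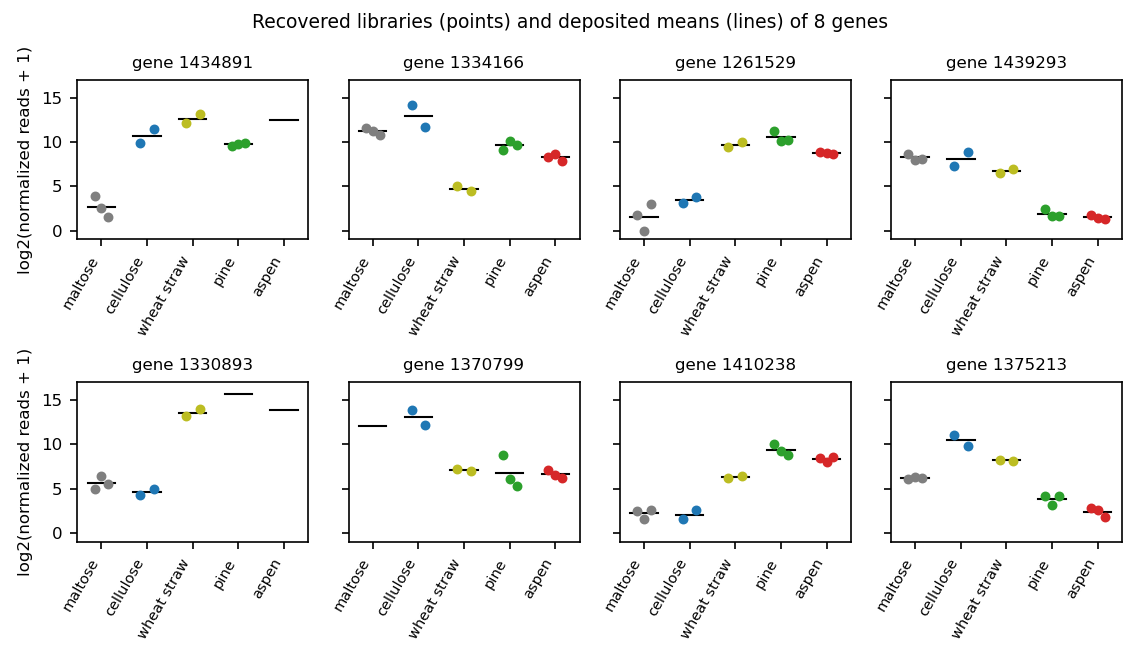
Log2(normalised reads + 1) of 8 named genes on each substrate, with points for the recovered libraries and lines for the deposited means; a line without points marks a mean whose libraries were not recovered. Gene 1261529 has means of 1.57 on maltose and 3.43 on cellulose and of 10.53 on pine, and gene 1375213 falls from 10.43 on cellulose to 2.37 on aspen.

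Pine and aspen were compared to set a softwood against a hardwood. The 2 woods differed less from each other than from maltose or cellulose: 173 genes were higher on pine and 68 higher on aspen, with median differences of 1.40 and -1.53, and no called difference reached 16-fold. Gene 1256766 was at 6.94 on pine (SD 0.02 over 3 libraries) and 4.37 on aspen (SD 0.28 over 3), a difference of 2.57 (SE 0.32, adjusted p = 0.000391). Gene 1318101 was higher on pine by 2.46 (SE 0.41, adjusted p = 0.00135). Gene 1327319 was lower on pine, with a difference of -3.41 (SE 0.75, adjusted p = 0.00513), though its pine libraries spread widely (SD 1.86 over 3, with 22 to 225 reads). Gene 302323 was lower on pine, with a difference of -3.07 (SE 0.50, adjusted p = 0.00126). The direction of the calls went with the level of the gene: 30.0% of the calls were higher on pine among the 263 genes of lowest mean level, and 95.1% among the 263 of highest. After quantile normalisation these shares were 57.1% and 55.1%. Of the 81 calls in the highest class only 1 was on a gene solved on both woods, so for the others the library spread of at least 1 wood is missing, and of all 241 calls 136 were on genes solved on both. In all, 71.8% of calls were higher on pine, against 53.8% with median centring, 57.9% after quantile normalisation and 56.7% with the median shift. On the 778 genes solved on pine, 80 were higher and 67 lower, and without pine library 1 this turned to 65 higher and 78 lower. With only the pine and aspen libraries in the fit, the genes higher on pine numbered 111.

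The woods were finally set against wheat straw, as the mean of pine and aspen minus wheat straw. Here 110 genes were higher on wood and 64 lower, with median differences of 1.48 and -1.54, the fewest calls of the 9 comparisons. Gene 1334166, which fell on wheat straw against maltose, was higher on wood by 4.20 (SE 0.52, adjusted p = 0.000315). Gene 1374787 was higher on wood by 3.64 (SE 0.51, adjusted p = 0.000613), at 9.48 on pine and 8.90 on aspen against 5.55 on wheat straw. Gene 1375213 was lower on wood, with a difference of -5.09 (SE 0.38, adjusted p = 1.67e-05), and so was gene 1439293, with -4.99 (SE 0.37, adjusted p = 1.67e-05). Without wheat straw library 1 this comparison gave 101 calls, and without library 2 it gave 112, against 173 on the same genes with both. The share of higher calls was 63.2%, against 62.4% with median centring, 51.8% after quantile normalisation and 47.7% with the median shift.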

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

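The test of changes of at least 16-fold under other scalings, those of single pine libraries and of the floor were stated in advance, and the tests of all called genes, of changes of at least 16-fold on cellulose and wheat straw alone and of the shallowest maltose library were chosen after their results were seen.

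Some genes moved in opposite directions on cellulose and on a plant material, each against maltose. There were 13 such genes for wheat straw, 23 for pine and 24 for aspen. Each was also called in the direct comparison of that material with cellulose, but the way these genes were chosen already sets a difference of at least 2 there, so this adds no independent evidence. In all, 32 genes were called opposite ways on cellulose and at least 1 plant material, 16 of them higher on cellulose and 16 lower. Of these 32 genes, 18 were still called opposite ways without cellulose library 1 and 24 without library 2, and of the 28 solved on maltose 18, 20 and 17 were without maltose libraries 1, 2 and 3. Without 1 wheat straw library 26 of 32 were, and of the 27 solved on a wood 24 to 27 were without 1 pine library and 21 or 22 without 1 aspen library. Without any 1 of the 13 libraries, each of these genes that was tested kept its opposite signs, so calls were lost through size or p-value. The totals over all genes tested were 31 and 37 without cellulose libraries 1 and 2, but 21, 24 and 18 without maltose libraries 1, 2 and 3, where the 28 genes are the total with all libraries. With the median shift there were 18, 28 and 26 such genes for wheat straw, pine and aspen. Pine and aspen had no gene called in opposite directions against maltose, and 1 with the median shift.

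More genes were higher than lower on every substrate against maltose, with 70.4% to 73.7% of calls higher. Fewer reads in the shallowest maltose library do not account for this, as shown on the 886 genes solved on maltose. Without that library 80.2%, 77.3%, 76.6% and 77.6% of calls were higher on cellulose, wheat straw, pine and aspen. With it, on the same genes, the shares were 76.5%, 75.8%, 74.6% and 76.6%. For the share over all calls the scaling between libraries stays open: it ranged down to 33.0% (wheat straw, each library centred on its median), and it was 61.8%, 60.2%, 55.4% and 56.6% on cellulose, wheat straw, pine and aspen with the median shift. None of the 4 scalings removed the excess among calls of at least 16-fold on cellulose and wheat straw. At least 42 were higher and none lower on cellulose, and on wheat straw the ratio was at least 3.87 (58 to 15 with median centring, lower 95% bound 2.16). The bounds come from exact binomial intervals that treat genes as independent, which genes of the same libraries are not. On the woods the lowest ratios were 1.34 on pine (47 to 35 with median centring, lower bound 0.849) and 1.68 on aspen (lower bound 1.06), and the ratio on pine is short of the margin of 1.5 set in advance for all 4 substrates. The direction of the excess over all calls, and among these large ones on the woods, therefore cannot be told apart from the scaling, because the table holds a part of the genes chosen by an unknown rule. A response to the substrate or to the lower maltose concentration, which is not known for aspen, is untested.

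Pine and aspen differed in a way that followed the level of the gene. The median difference, pine minus aspen, was -0.39 in the 263 genes of lowest mean level and 0.66 in the 263 of highest, 1.05 apart (bootstrap SE 0.0715 over genes). Between the lowest and the third of 4 equal classes by level, it does not come from a single pine library. Against the aspen mean, pine libraries 1, 2 and 3 lay higher in the third class, by 0.87, 0.56 and 0.64 (SE 0.0866, 0.106 and 0.0876). In the highest class only 21 of 263 genes were solved on both woods, so single libraries could not be checked there. The difference with level does not rest on genes near the floor, since the highest class lay 0.84 (SE 0.0807) above the second. After quantile normalisation, which forces equal distributions, the medians were -0.04 and 0.07, so the distribution of values as a whole, whether from the wood or from library preparation, may account for it. No batch is given in the labels, and a difference between the woods is untested.

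Splitting the 6 libraries of 2 substrates into other groups of 3 gives 10 splits with the real one, too few for a share under 0.05. On the solved genes, the real split called 338 genes for pine against maltose, 305 for aspen against maltose and 135 for pine against aspen, the highest other split called 0, and in each case 1 of 10 splits reached the real number.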

How the results depend on the processing

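No paired analysis was possible because the table carries no replicate numbers, so the planned replicate block was not run, nor were the gene lists and their estimated correlation. No named gene changed sign, but the balance of higher and lower calls did: lower calls outnumbered higher ones in all 4 comparisons with maltose under median centring and quantile normalisation, for wheat straw against cellulose under median centring, for wood against straw with the median shift (82 higher, 90 lower), and, on the solved genes, without pine library 1 for pine against aspen (45.5% higher) and pine against cellulose (49.1%, against 50.4% with it). Of the alternatives to a count, 407 stayed within 1.5 times and 157 did not; of those to a named gene, 571 kept the call and 3 lost it. Spread without a trend and library weights moved no count by over 1.5 times. Where genes were left out, fewer genes were tested, which can lower counts, but how much of each fall this explains was not tested. Elsewhere the cause was not tested. The effect of depth itself was not tested.

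Higher on pine than aspen were 111 genes with only the libraries compared. Without the lowest 25% of genes by level, 91 were lower on pine than maltose, 40 lower on pine than aspen, and 11 lower than maltose on all 4. With 32 reads added, 38 were lower on cellulose than maltose and 42 lower on pine than aspen.

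With median centring, higher and lower calls against maltose were 170 and 346 on wheat straw, 243 and 349 on pine, and 224 and 317 on aspen; 205 were lower on cellulose and 115 lower on pine than aspen. Higher and lower than maltose on all 4 were 64 and 75; on all 3 plant materials against maltose and cellulose, 72 and 77. After quantile normalisation, lower against maltose were 153 on cellulose, 274 on wheat straw, 306 on pine (249 higher) and 308 on aspen; 106 were higher on pine than aspen, 70 lower on all 4, and 73 lower on all 3 plant materials. With the median shift, chosen after seeing the data, lower calls were 94 on cellulose and 241 on pine against maltose, and 107 on pine against aspen.

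By adjusted p alone, lower than maltose were 221 on pine and 224 on aspen. Pine and aspen differed in 448 genes (290 higher on pine, 158 lower), wood and straw in 300 (193 higher on wood, 107 lower). At a minimum difference of 2, calls (higher, lower) against maltose were 113 (97, 16) on cellulose, 214 (166, 48) on wheat straw, 320 (252, 68) on pine and 279 (209, 70) on aspen. Against cellulose they were 149 (94, 55), 252 (161, 91) and 216 (130, 86). Pine against aspen gave 36 (23, 13) and wood against straw 49 (34, 15). The 4 groups had 61 higher and 6 lower on all 4, and 52 higher and 14 lower on the plant materials.

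On the 707 genes solved in all libraries, also chosen after seeing the data, calls (higher) against maltose were 128 (85), 208 (129), 309 (193) and 292 (193) on cellulose, wheat straw, pine and aspen. Against cellulose they were 202 (112), 296 (155) and 282 (163). Pine against aspen gave 131 (75), wood against straw 100 (59 higher, 41 lower), and 533 genes differed among the 5 substrates. Higher on all 4 were 37, and higher on the plant materials 52.

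Leaving out 1 library at a time tests only genes solved in its substrate. Calls ranged from 347 to 455 for pine against maltose (210 to 340 higher), 316 to 407 for aspen (193 to 315 higher, 91 to 125 lower), 38 to 80 lower on cellulose and 67 to 93 lower on wheat straw. Against cellulose they were 318 to 469 on pine (166 to 292 higher), 150 to 252 higher on aspen and 70 to 129 lower on wheat straw. Pine against aspen gave 128 to 169 (65 to 110 higher, 42 to 78 lower) and wood against straw 101 to 131 (58 to 75 higher, 36 to 65 lower). Groups ran from 40 to 114 and 10 to 22 genes (higher and lower on all 4), and 53 to 113 and 20 to 37 (plant materials). On the same genes, wheat straw 1 and 2 moved counts of the 9 comparisons and 4 groups by over 1.5 times: wood against straw fell from 173 to 101 and 112, and without wheat straw 2 the group of 36 fell to 20 and the genes lower on wheat straw than maltose and cellulose to 67 and 70. Of the genes called opposite ways on cellulose and a plant material, 18 of 32 kept this without cellulose 1, and 18 of 28 and 17 of 28 without maltose 1 and 3, where the total over all genes was 21 and 18.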

Other observations

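For the set of 51 genes, the tests on random lists and single pine libraries were stated before their results were seen, and the set was chosen because the named genes with the largest rises on cellulose had their lowest plant value on pine.

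Most of the genes that rose most on cellulose were also called higher on the plant materials, with their lowest median on pine. A set of 51 genes rose at least 16-fold on cellulose against maltose, by a median of 6.85 on the log2 scale. Their median difference from maltose was 5.95 on wheat straw, 5.91 on aspen and 4.70 on pine. Of the 51, 46 were called higher than maltose on all 3 plant materials, 1 was called lower on at least 1 of them, and 40 had the lowest of their 3 plant values on pine. Between the woods, 41 of the 51 were lower on pine than on aspen, with a median difference of -0.89, but only 9 were called lower and 3 were called higher. The median ran against the general direction at their level: random lists of 51 genes matched on level had medians between 0.091 and 0.65 in the middle 95% of 10000 lists, and none was as low. With 1 pine library left out at a time, the median of the 19 genes solved on both woods stayed below 0, at most -0.54. Under the other scalings it lay between -1.35 and -1.05 for the 51 genes. Against wheat straw, 47 of the 51 were lower on wood, the mean of pine and aspen, with a median difference of -0.995, and 9 were called lower and none higher. The order of the medians against maltose does not extend to all 168 genes called higher on cellulose. Their medians were 2.55 on pine, 2.54 on aspen and 2.23 on wheat straw, and 25 were called higher on pine than aspen against 13 lower. Yet the median of their differences, pine minus aspen, was -0.129, with 94 of the 168 below 0. Random lists matched on level had medians between 0.149 and 0.471 in the middle 95%, and none of 10000 was as low. The 168 include the 51, and the rest were not tested alone. Random lists were drawn gene by gene, as if genes were independent, but both sets share a rise on cellulose and may vary together between libraries. The number of lists as low is therefore no p-value for a difference between the woods. A weaker response on pine than on aspen of these 51 genes is a hypothesis, found on the same data. The matched lists bear only on the difference that followed level, and the left-out libraries only on single pine libraries. Whether a weaker response is particular to the 51 was not tested. The added maltose of the aspen cultures, misprinted in the labels, may also differ.

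The 113 genes higher on all 3 plant materials than on maltose and cellulose had a median difference, pine minus aspen, of 0.56, with 31 called higher on pine and 7 called lower. The median was 0.37 with median centring, 0.12 after quantile normalisation and 0.39 with the median shift. The pine and aspen values also defined this set, so these values are a description and no test. Against wheat straw they were higher on wood by a median of 0.55, with 26 called higher and 1 called lower.

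The cellulose column is a mean of 2 libraries although 3 cellulose samples are labelled, while every other column holds as many libraries as the labels list. Of the genes solved on cellulose, 10.6% had an SD of at least 1, the highest share of the 5 substrates, and the median SD was 0.29, against 0.31 on pine. Neither measure ranks the spread of the substrates, since cellulose has 2 libraries and 1048 solved genes, and pine 3 libraries and 778.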
